A study of Homo sapiens with 5 samples.

How the data were processed

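Gene expression was measured in LNCaP cells, an established androgen-responsive prostate cancer line, on 5 Agilent oligonucleotide arrays (design 012391) read in Cy5 and Cy3. Each array compared a test RNA in Cy5 with a common reference RNA in Cy3, from untransduced cells that had received no dihydrotestosterone (DHT). The 5 groups, with 1 sample and 1 array each, were untransduced cells with DHT, cells with a control hairpin (shCon) without and with DHT, and cells with a hairpin against RNF6 (shRNF6) without and with DHT. The labels give a DHT dose, 1 nM, only for the untransduced cells. They give no duration, no number of cultures and no number of RNF6 hairpins. The dyes were never swapped. The 5 arrays came from 5 slides and 1 scan day. The RNA extraction and labelling steps are described in the sources only by reference to the manufacturer.

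The authors scanned the arrays and quantified the spots with Feature Extraction 9.5.3.1. Per the file headers, the mean and local background signals of each channel are intensity in arbitrary scanner units. Also per the file headers, the processed signals are intensity after background subtraction, spatial and multiplicative detrending and dye normalization, with dim spots replaced by surrogate values. The deposited log ratio is log10 of processed red over processed green, and was checked to be 0 where both signals lay near background.

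Each array held 43931 spots: 2256 control spots and 41675 others, which carried 41000 distinct probes, 75 of them on 10 spots each. Mean signals were background-corrected with limma's normexp method (offset 50), and log2 ratios of Cy5 over Cy3 were normalized by loess within each array, with control spots at weight 0. Spots that Feature Extraction marked as outliers were removed, and replicate spots of a probe were averaged. A probe was kept if Cy5 was well above background, by Feature Extraction's own test (multiplier 13, significance 0.01), on at least 2 arrays; this left 11397 probes. Probe names came from RefSeq annotation: 23680 by accession, 2802 by symbol and 1128 by a unique synonym, and 13390 kept the file's name. The brightest probe stood for each gene, which gave 9565 genes. Probe coordinates are those in the array files, whose genome build is not given in the sources used here. Where in its transcript a probe lies was not determined.

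Because every array shared the same reference, a difference of 2 log2 ratios compares their Cy5 samples. The depth of the arrays differed: 12458 probes were well above background in Cy5 for shCon without DHT, 12490 for untransduced with DHT, 6570 for shCon with DHT, 5328 for shRNF6 with DHT and 5489 for shRNF6 without DHT. The SD of log2 ratios between replicate spots of a probe, which measures technical precision within an array only, was 0.08, 0.10, 0.13, 0.09 and 0.25 in the same order. The last of these rests on 4 probes.

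A limma fit on the 4 hairpin arrays estimated a DHT effect and an shRNF6 effect as additive terms, with 1 residual degree of freedom. That degree of freedom holds the noise and any interaction, so a gene whose DHT response differed between hairpins tends to lose its call. Moderated p-values were adjusted over all 9565 genes by the Benjamini-Hochberg method at 0.05. Nothing in the sources says that the arrays come from separate cultures, so the p-values measure only the spread between these samples. All other comparisons (DHT within each background, shRNF6 over shCon with and without DHT, the difference of DHT responses, shCon over untransduced) have no replicate and are given as values. Relations between comparisons are Pearson or Spearman correlations over genes, computed between comparisons that share no test array; genes are not independent replicates, so no p-value is attached.

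Where a gene was well above background in Cy5 on one side of a comparison alone, the fold is given as "at least". For this bound, a dim-side Cy5 signal below the dimmest signal called well above background on its array was raised to that signal. It was divided by the spot's own Cy3, so a bound is never larger than the fold from the log2 ratios. A dim-side signal already brighter than that was kept, so such a bound equals the fold from the log2 ratios. Error in Cy3, which was also dim for some genes, is not covered by a bound. A first form of the bound, from Cy5 alone after between-array scaling, exceeded the ratios of several genes and was replaced after the values were seen; it served only to pick genes to name. A bound not above 1-fold is not given. Fitted log2 changes, their p-values and list medians use the measured ratios, whether or not each signal was above background.

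A set of 21 gene lists, the processing, the alternatives and the rule for naming genes were fixed before the data were examined. The naming rule took genes well above background in both channels on all 5 arrays, in order of absolute change. For DHT, these were called genes with the same direction in all 3 backgrounds, then uncalled genes changed at least 1.5-fold in all 3, up to 12 per direction. For shRNF6, they were called genes changed at least 1.5-fold both with and without DHT, up to 10 per direction. The difference of responses took genes measured in Cy5 on the 4 hairpin arrays with an at least 2-fold response in 1 arm, up to 8 per direction. The comparison of shCon with untransduced cells took genes at least 1.5-fold different with and without DHT, up to 5 per direction, and the Cy5 bounds took the 3 largest per direction. RNF6 was named whatever its value. For a list, the examples are the members with the largest absolute fitted change. Each list's median was ranked among 10000 random lists matched for brightness in 10 bins (seed 1), and the Benjamini-Hochberg adjustment was also run over the list's members alone. Both counts are given.

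The tests were run on simulated data with the same number of arrays and genes: 20 simulations of 9565 genes with 200 changed genes, 50 at each of 4 sizes. The fit recovered a median of 89% of 1.5-fold changes for the shRNF6 term (lowest 76%, highest 100%) and 87% for the DHT term (62% to 98%), and at least 98% of 2-fold changes in each simulation. The false share of calls had a median of 10.95% (4.1% to 19.7%) for the shRNF6 term and 8.3% (3.2% to 17.1%) for DHT. This was above the nominal 5%, so even in this setting the adjusted p-values were too small. The simulated noise was independent between genes and arrays, without interaction or uneven slides, whereas 30.96% of genes were called for shRNF6 in the data. These shares may therefore not hold for the real calls. Where a term had no changed gene, it gave 0 to 14 calls for shRNF6 and 0 to 8 for DHT. A shifted list reached percentile 100, and 0 of 20 unshifted lists lay outside the central range of random lists.

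The alternatives were Agilent's processed signals, no background correction, no filter on brightness, a filter for signals well above background in both channels on all arrays, the mean of a gene's probes, median centring in place of loess, Aquantile scaling between arrays, an intensity trend in the moderation, all 5 arrays in 1 fit, the untransduced arrays in place of a hairpin arm, and a 1.5-fold threshold. Removal of a spatial trend (span 0.1), centring on the tested genes and 4 further gene lists were added after values had been seen. So was the untransduced control in place of shCon for the shRNF6 term. A few genes are not reported here. The gene TMPRSS2 was excluded from the tested genes because its spot was marked as an outlier on 1 array.

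Computation used R 4.3.3, limma 3.58.1, the package data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.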

Results

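LNCaP prostate cancer cells carrying a control hairpin (shCon) or a hairpin against RNF6 (shRNF6) were profiled without and with dihydrotestosterone (DHT), beside untransduced cells with DHT. RNF6 is a ubiquitin ligase, and the comparisons address how it shapes the cells' transcriptional response to androgen and the choice of target genes. Each of the 5 groups had 1 array, with no replicates, and log2 ratios compare the sample in Cy5 with untransduced cells without DHT in Cy3. The DHT response of untransduced cells is the ratio of the dyes on 1 array, so dye effects of single genes enter it, whereas they cancel in the responses of the hairpin arms. The small number of arrays limits the precision of every value below.

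RNF6 itself read lower in the shRNF6 cells, at signals mostly too dim for a fold. Its log2 ratio to the reference was 0.06 in shCon without DHT, -0.03 in untransduced cells with DHT, 0.03 in shCon with DHT, -0.63 in shRNF6 without DHT and -0.55 in shRNF6 with DHT. Over the 4 hairpin arrays RNF6 fell by 0.63 on the log2 scale (SE 0.09, adjusted p = 0.00243), with -0.69 without and -0.58 with DHT. The probe lies on chromosome 13 from 25685305 to 25685364, build not given in the sources used here, and was well above background on the shCon array without DHT and the untransduced array alone. These differences and their p therefore rest in part on 3 hairpin arrays with signals not above background, and no fold or bound is given. A second RNF6 probe was well above background on none of the arrays and read 0.23 and 0.29 higher in shRNF6 without and with DHT.

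DHT raised genes of the androgen programme in the cells with hairpins. SLC45A3, which encodes prostein, rose by 1.35 on the log2 scale (SE 0.10, adjusted p = 0.00981), and MPC2, a subunit of the mitochondrial pyruvate carrier, rose by 0.95 (SE 0.10, adjusted p = 0.0429). In untransduced, shCon and shRNF6 cells, the log2 responses to DHT were 1.62, 1.22 and 1.48 for SLC45A3 and 1.18, 1.03 and 0.86 for MPC2. DEGS1, a ceramide desaturase, and DBI, which binds acyl-CoA, were higher with DHT in all 3 backgrounds (0.93, 0.66 and 1.03; 0.85, 0.85 and 0.60) but did not pass the test, with adjusted p of 0.0857 and 0.102. DDC, aromatic amino acid decarboxylase, was lower in all 3 (-1.23, -1.06 and -0.65; adjusted p = 0.0952).

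Of 21 measured androgen-induced genes, 2 rose with DHT over all genes and 11 when adjusted over the list alone. The list's median response was 0.42 in untransduced, 0.25 in shCon and 0.29 in shRNF6 cells, above all 10000 random lists in each (percentile 100). KLK2, a kallikrein, gave 1.32 in untransduced and 0.17 in shCon cells, was at least 1.27-fold higher with DHT in shRNF6 cells, and passed over the list alone. The brightest probe for KLK3, the gene of prostate-specific antigen, gave -0.38, 0.20 and 0.11. Another of its probes gave 1.56, 1.11 and 0.93, and a further one 0.92, 0.28 and 0.52. The probes of KLK3 thus disagreed, with only the brightest lower with DHT in untransduced cells.

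Of 18 measured S phase and DNA replication genes, none passed over all genes and 10 rose over the list alone. Their medians were 0.50, 0.38 and 0.27 in untransduced, shCon and shRNF6 cells (percentile 100 in each). The sliding clamp PCNA (0.89, 0.72 and 0.40), the methylation factor UHRF1 (0.52, 0.85 and 0.33) and the replicative helicase subunit MCM3 (0.68, 0.60 and 0.44) had the largest fitted responses, with UHRF1 and MCM3 well above background on neither shRNF6 array. Of 15 unfolded protein response and secretory genes, none passed over all genes and 10 rose over the list alone, with medians of 0.25, 0.24 and 0.27 (percentile 100 in each). Examples were CREB3L4, a membrane-bound transcription factor (0.43, 0.71 and 0.41), and SDF2L1, an endoplasmic reticulum chaperone component (0.64, 0.42 and 0.41).

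Lipid and polyamine genes were higher as lists too. Of 18 sterol synthesis genes, none passed over all genes and 5 rose over the list alone; the medians were 0.34, 0.23 and 0.20 (percentiles 100, 100 and 99.96). Of 11 fatty acid synthesis genes, 2 rose over the list alone and none over all genes, with medians of 0.24, 0.20 and 0.18, although the shCon median became -0.0005 with median centring; the elongase ELOVL5 gave 0.84, 0.55 and, well above background on neither shRNF6 array, 0.56. Of 8 polyamine synthesis genes, 4 rose over the list alone and none over all genes, with medians of 0.35, 0.22 and 0.28 (percentiles 99.99, 99.93 and 99.82); AMD1, which makes decarboxylated S-adenosylmethionine, gave 0.28, 0.34 and 0.92.

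Of 14 measured androgen-repressed genes, none passed the DHT test over all genes; over the list alone 5 fell and 1, TMEFF2, rose. The list's median was -0.53 in untransduced and -0.40 in shCon cells, both below all random lists (percentile 0), and -0.02 in shRNF6 cells (percentile 3.34). With processed signals the shRNF6 median was -0.39, close to the -0.51 of shCon, and with median centring the untransduced median turned to 0.13. Mitosis genes (13 measured) had medians of 0.06, 0.17 and 0.10, with 3 rising over the list alone. Of 11 heat shock genes, 2 rose over the list alone, among them HSPE1, a mitochondrial co-chaperonin (0.48, 0.38 and 0.43); the list's medians were 0.17, 0.06 and 0.01, and the shCon median turned to -0.06 with Agilent's processed signals. Of 14 housekeeping genes, 2 rose over the list alone (medians 0.06, 0.10 and 0.20; the untransduced median was -0.02 with processed signals). Of 13 luminal epithelial markers 1 rose, over all genes and over the list alone, with medians of -0.06, 0.12 and 0.11 (untransduced 0.66 with median centring).

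No member of the remaining lists passed for DHT, over all genes or the list alone. Their medians in untransduced, shCon and shRNF6 cells were -0.04, -0.11 and 0.20 for interferon-stimulated genes, -0.17, -0.13 and 0.08 for p53 targets, -0.06, 0.03 and 0.10 for ATF4 targets, -0.01, 0.05 and 0.12 for glycolysis, -0.04, 0.02 and -0.05 for ribosomal proteins, and -0.12, -0.02 and -0.13 for metallothioneins. For coregulators of the androgen response they were -0.02, -0.09 and -0.04, for neuroendocrine markers -0.06, 0.03 and 0.03, for basal markers -0.01, -0.03 and 0.06, and for fibroblast and stromal markers -0.22, -0.12 and 0.09. Under other scalings at least 1 of the 3 medians changed sign for each of these 10 lists.

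**Figure D1:**
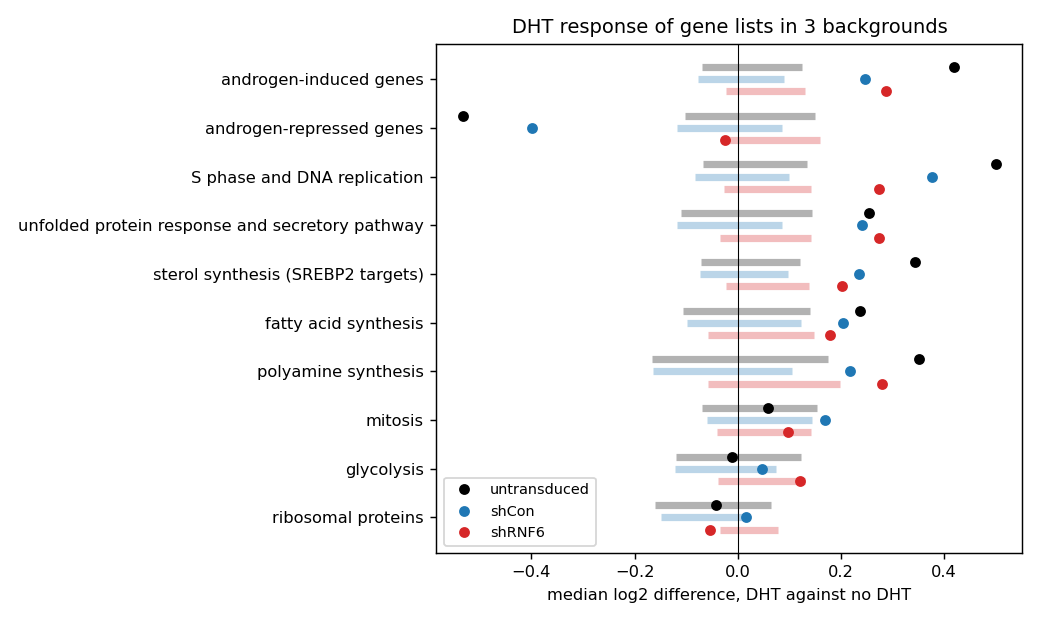
Median log2 response to DHT of 10 gene lists (x axis) in untransduced, shCon and shRNF6 cells, 1 array per group; points are list medians and bars the central range of 10000 random lists matched for brightness. The androgen-repressed genes were lower in untransduced (-0.53) and shCon cells (-0.40) and near 0 in shRNF6 cells (-0.02), though at -0.39 there with Agilent's processed signals.

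The limma fit for DHT used 4 arrays with 1 residual degree of freedom and called 3 genes higher and 0 lower of 9565, with 968 at unadjusted p under 0.05 where chance gives 478. In the simulations a DHT term without changed genes gave 0 to 8 calls, a range that includes these 3. At least 2-fold changes with DHT numbered 13 higher and 7 lower in untransduced cells, 8 and 5 in shCon cells, and 7 and 2 in shRNF6 cells. The count depended on the setting: 0 genes rose with processed signals, and 280 rose in a fit of all 5 arrays. Dye effects of single genes enter the latter fit through the untransduced array, so its 280 genes may include them. Over the alternatives the adjusted p ranged from 9.79e-11 to 0.306 for SLC45A3 and from 8.7e-07 to 0.337 for MPC2, each highest with processed signals. With signals required well above background in both channels on all arrays, MPC2 also lost its call (adjusted p = 0.163), as it did with median centring (adjusted p = 0.165) and with the mean of a gene's probes (adjusted p = 0.0572).

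Interferon-stimulated genes were far higher in shRNF6 than in shCon cells. All 17 measured members, of 22 listed, rose, over all genes and over the list alone, with a median log2 change of 2.89 without and 2.83 with DHT (percentile 100 in both). IFIT2, an antiviral RNA-binding protein, rose 138-fold without DHT and at least 160-fold with DHT (fitted log2 7.37, SE 0.13, adjusted p = 3.09e-07), although it lost its call with an intensity trend in the moderation (adjusted p = 0.292, the highest over the alternatives, whose lowest was 3.82e-34). Its fitted log2 change ranged from 5.36 to 9.34 over the alternatives, so the fold is uncertain. OASL, an oligoadenylate synthetase-like protein, was 41.7-fold and at least 33.8-fold higher without and with DHT, and IFIT1, a relative of IFIT2, at least 31.5-fold and at least 23.5-fold. IFIT1 passed the brightness filter through the shRNF6 arrays alone, so the share of members that rose is partly set by that filter. Among the smallest changes were those of OAS3 (1.55-fold and at least 1.64-fold) and IRF9, a subunit of the interferon-activated factor ISGF3 (at least 1.75-fold and at least 1.36-fold). The same list was at log2 0.03 in shCon over untransduced cells, both without and with DHT, though without DHT this became -0.13 with processed signals.

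Among genes well above background on all arrays, the largest rises in shRNF6 cells were those of ISG20, an interferon-induced exonuclease (log2 3.55), ISG15, a ubiquitin-like modifier (3.16, with its Cy5 spot saturated on 2 arrays, so its size and rank are uncertain), NUPR1, a stress-induced chromatin protein (3.12), CEBPB, a transcription factor (8.55-fold), PLAAT4 (2.98), CSAG3 (2.94), CSAG2 (2.93), SQOR, a mitochondrial sulfide oxidoreductase (2.91), TFF1, a secreted trefoil peptide (2.80), and B2M, the light chain of HLA class I (2.74). Their adjusted p ranged from 9.97e-07 to 7.96e-06. CSAG2 and CSAG3 are near-identical paralogs, so which of them changed is uncertain. The largest falls were those of EIF4B, a translation initiation factor (log2 -1.33, adjusted p = 5.1e-05), DDC (-1.32), SPON2 (-1.18), FOLH1, which encodes prostate-specific membrane antigen (-1.14), FOLH1B (-1.13), SNHG8 (-1.10), the metalloreductase STEAP2 (-1.05), FARSB, a subunit of phenylalanyl-tRNA synthetase (-1.03), and ACAT1, a mitochondrial thiolase (-1.02). FOLH1 and FOLH1B are also near-identical. DDC, FOLH1 and FOLH1B lost their calls with an intensity trend in the moderation, and DDC and ACAT1 with processed signals.

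**Figure D2:**
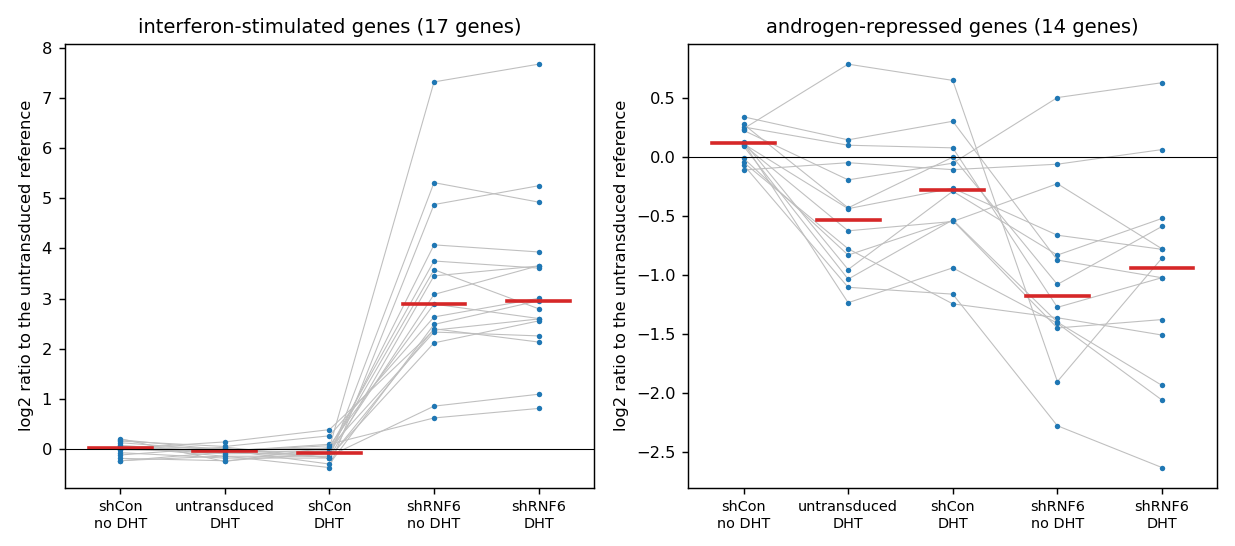
Log2 ratio of each of the 5 samples to untransduced cells without DHT (y axis) for 17 interferon-stimulated and 14 androgen-repressed genes; points are genes, grey lines join a gene across arrays and red bars are medians. The interferon-stimulated genes were higher on both shRNF6 arrays, with medians of 2.89 without and 2.83 with DHT over shCon, and the androgen-repressed genes lower, at -1.34 and -0.71.

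Androgen-repressed genes were lower in shRNF6 cells: 11 of 14 fell and 1, the acid phosphatase ACP3 (log2 0.48), rose (12 and 1 over the list alone). Their median was -1.34 without and -0.71 with DHT, below all random lists. UGT2B15, which glucuronidates androgens, fell at least 4.18-fold and at least 1.89-fold without and with DHT, TMEFF2, a transmembrane proteoglycan, at least 3.4-fold and 2.84-fold, and the chemokine receptor ACKR3 at least 2.07-fold and at least 1.92-fold. Of 21 androgen-induced genes 7 rose and 3 fell (7 and 5 over the list alone), with medians of -0.15 and -0.003 that turned positive with processed signals (0.10 and 0.24). ACSL3, an acyl-CoA synthetase, was at least 1.98-fold and at least 1.65-fold higher, the sorbitol dehydrogenase SORD rose by log2 0.89, KLK3 by 0.77 at its brightest probe and KRT8, a luminal keratin, by 0.75. Another KLK3 probe read -1.33 and -1.50 and a further one -0.50 and -0.25. The probe at -1.33 and -1.50 is the only KLK3 probe annotated to a RefSeq transcript, and was well above background on neither shRNF6 array. Only the brightest probe read higher, so the direction for KLK3 is uncertain. In the list KLK3 is counted by that brightest probe.

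Most S phase genes and 6 of 13 mitosis genes fell in shRNF6 cells. Of 18 S phase genes 13 fell and none rose, over all genes and over the list alone, with medians of -0.39 without DHT (percentile 0.09) and -0.56 with DHT (percentile 0). With processed signals these medians were -0.80 and -1.11, so their size depended on the scaling. MCM3 was at least 1.73-fold and at least 1.93-fold lower without and with DHT, CDC45, a helicase component, at least 1.06-fold and at least 1.67-fold, and TYMS, thymidylate synthase, at least 1.24-fold and at least 1.55-fold. Of 13 mitosis genes 6 fell and none rose, with medians of -0.20 and -0.28 (percentiles 11 and 2.26, the first inside the central range of random lists); the survivin gene BIRC5 fell by 0.73 on the log2 scale and the mitotic kinase CDK1 was at least 1.56-fold lower with DHT. These falls lay on arrays with fewer probes above background: 5489 and 5328 for shRNF6 without and with DHT, against 12458 and 6570 for shCon.

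Most secretory genes and 4 of 8 polyamine genes fell too, while most lipid genes did not pass. Of all 9565 genes the fit called 1993 lower. Without and with DHT the medians below lay at percentiles 9.01 and 0.95 for sterol and 22.89 and 41.85 for fatty acid genes. Polyamine medians lay at 2.11 and 3.92. The sterol median without DHT, both fatty acid medians and the polyamine median with DHT lay inside the central range of random lists. Of 15 unfolded protein response and secretory genes 10 fell and 1, the transcription factor XBP1, rose 5.24-fold (adjusted p = 3.54e-06), with the same counts over the list alone and medians of -0.33 and -0.42. With median centring these medians were -0.95 and -1.02. The largest falls were those of CREB3L4 (log2 -0.95), HERPUD1, a component of endoplasmic reticulum-associated degradation (-0.86), and HSPA5, the main chaperone of that compartment (at least 1.39-fold lower without DHT). Of 18 sterol synthesis genes 8 fell and 1 rose (9 and 1 over the list alone), with medians of -0.21 and -0.26; without DHT the median turned to 0.06 with processed signals. The sterol desaturase SC5D was at least 1.12-fold lower without DHT. Of 11 fatty acid genes 3 fell, SREBF1 (-0.73), ELOVL5 (at least 1.58-fold lower with DHT) and the desaturase SCD (not above background on the shRNF6 arrays, with no bound), and ACSL3 rose (3 and 1 over the list alone), with medians of -0.15 and -0.07, the latter 0.002 when arrays were centred on the tested genes. Of 8 polyamine genes 4 fell and SAT1, which acetylates polyamines, rose by log2 0.84 (4 and 1 over the list alone); the arginase ARG2 was at least 1.45-fold and at least 1.81-fold lower, and the list's medians were -0.40 and -0.25.

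Stress genes went both ways. Of 14 ATF4 targets 5 rose and 6 fell, over all genes and the list alone, led by CEBPB and by ATF3, a stress-induced transcription factor (3.00-fold without and at least 4.69-fold with DHT), against SHMT2 (log2 -0.69) and TRIB3 (-0.67); the medians of -0.19 and -0.08 turned positive with processed signals (0.14 and 0.19). Of 13 p53 targets 6 rose and 2 fell (8 and 2 over the list alone), with GDF15, a secreted stress cytokine, 4.09-fold and 5.37-fold higher, PHLDA3 2.25-fold and at least 1.77-fold higher and TP53INP1 1.75-fold and at least 1.71-fold lower; the fitted median of 0.36 turned to -0.09 with median centring. Of 8 metallothioneins, metal-binding proteins, 6 rose and none fell, with medians of 1.23 and 1.15 (percentiles 100 and 99.99) and MT1H, MT2A and MT1G at 1.35, 1.32 and 1.30; cross-hybridisation among these paralogs leaves the member uncertain. Of 11 heat shock genes 2 fell, HSPE1 (-0.90) and HSP90AB1 (-0.44), with list medians of -0.11 and -0.15 that turned to 0.12 and 0.20 with processed signals.

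In the remaining lists calls were few or went both ways. Of 13 luminal markers 5 rose and 3 fell (6 and 4 over the list alone), among them KRT18 (log2 0.84), with medians of -0.04 and -0.06 that turned to 0.31 and 0.41 with processed signals. Of 3 neuroendocrine markers TUBB3 rose (0.35) and SYT4 fell (at least 1.85-fold and at least 1.2-fold), with medians of 0.04 and 0.04 (-0.25 and -0.40 with median centring). Of 2 basal markers none passed (medians 0.01 and 0.10; -0.15 and -0.20 with processed signals). Of 3 fibroblast and stromal markers FN1, fibronectin, rose 2.10-fold and at least 2.75-fold without and with DHT, with medians of -0.10 and 0.39 that changed sign under other scalings. Of 15 coregulators of the androgen response 2 rose, among them TRIM24 (0.72), and 4 fell, among them the ubiquitin ligase UBE3A (at least 1.09-fold lower without DHT), with medians of -0.09 and -0.08; without DHT this was 0.01 when arrays were centred on the tested genes. Of 16 glycolysis genes ALDOA rose (0.44) and PFKM (at least 1.81-fold and 1.80-fold) and LDHA (log2 -0.46) fell, with medians of -0.15 and -0.04, the latter 0.03 with that centring. Of 30 ribosomal protein genes 1 rose and 5 fell (1 and 3 over the list alone), RPLP1 at 0.73 (saturated in Cy5 on 1 array) and RPL5 at -0.71, with medians of 0.06 and -0.02 against -1.01 and -0.95 with median centring. Of 14 housekeeping genes 2 rose, among them B2M (2.74), and 2 fell, among them TFRC (1.84-fold and at least 2.36-fold), with medians of -0.03 and 0.01 against 0.08 when centred on the tested genes without DHT and -0.44 with median centring with DHT. For the mitosis, metallothionein, heat shock, neuroendocrine, basal, stromal, coregulator, glycolysis and housekeeping lists the counts over the list alone were the same.

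For shRNF6 the limma fit on 4 arrays called 968 genes higher and 1993 lower of 9565 (30.96%), 264 and 46 of them at least 2-fold. The balance depended on the scaling: 32.69% of the called genes were higher as fitted here, 54.68% with processed signals (1128 and 935 genes), 50.48% when centred on the tested genes and 9.85% with median centring. At least 2-fold changes numbered 263 higher and 83 lower without DHT and 276 and 54 with DHT, of which 224 and 28 were shared, and the changes without and with DHT correlated at r = 0.88 (rho 0.75, 9565 genes). Both shRNF6 arrays had brighter negative-control spots on the right side of the slide (Cy5 medians 168.4 and 240 without and with DHT) than the other arrays (84 to 118.7). The spike-in correlation given by Feature Extraction was 0.84 on both, against 0.94 to 0.99 on the other arrays. Among the hairpin arrays these features went with the hairpin, so their effects cannot be separated in the fit.

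The DHT response differed between the hairpins for genes lowered by DHT. Of 59 genes at least 1.5-fold lower with DHT in untransduced cells, a choice that dye effects enter (the log2 ratios of that array and of shCon without DHT correlated at 0.44 over all spots), the median response was -0.71 there, -0.42 in shCon and -0.004 in shRNF6 cells; 47 were more positive in shRNF6, by a median of 0.41 (0.27 with processed signals). Of 99 genes at least 1.5-fold higher in untransduced cells (median 0.70), the medians were 0.43 in shCon and 0.33 in shRNF6, a median difference of -0.13 that turned to 0.002 with processed signals and 0.14 with median centring. At least 1.5-fold responses in the same direction were found in shCon for 10 of the lowered and 32 of the raised genes, and in shRNF6 for 1 and 15. In the fixed androgen-repressed list 13 of 14 genes were more positive in shRNF6, by a median of 0.42 (percentile 100); with processed signals the list's medians were -0.51 in shCon and -0.39 in shRNF6.

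By gene, ATP1B1, a subunit of the sodium pump, was lower with DHT in untransduced (-1.10) and shCon cells (-1.24) but not in shRNF6 cells (0.06), a difference of 1.30. HMGB2, a chromatin protein, went from 0.44 in shCon to 1.09 in shRNF6 (difference 0.64), the exchange factor gene ARHGEF26 from 0.52 to 1.14 (0.62), and FRMD4A from -0.42 to -1.08 (-0.66). Differences were 0.41 for DDC, 0.37 for DEGS1, 0.26 for SLC45A3 and -0.17 for MPC2. Across all genes 8 differed by at least 2-fold upward and 6 downward. These differences rest on 4 arrays with 1 per group and have no test. The response in shCon correlated with that in shRNF6 at r = 0.24 over 9565 genes and r = 0.64 over the 158 genes above, and with that in untransduced cells at 0.49, against 0.31 for shRNF6 with untransduced cells.

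**Figure D3:**
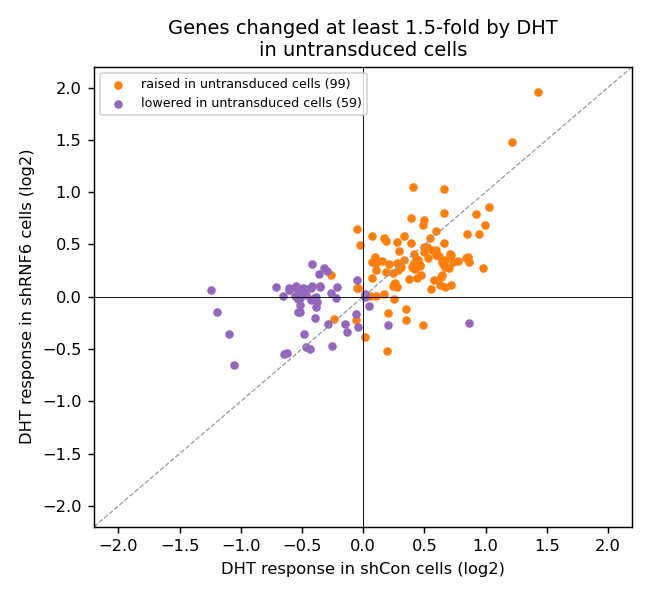
Log2 response to DHT in shCon cells (x axis) and in shRNF6 cells (y axis) for 158 genes at least 1.5-fold changed by DHT in untransduced cells, 1 array per group; each point is a gene, 99 raised ones in orange and 59 lowered ones in purple, and the dashed line marks equal responses. The lowered genes lay at a median of -0.42 in shCon and -0.004 in shRNF6 cells, the raised ones at 0.43 and 0.33.

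Between shCon and untransduced cells few genes differed by much. FAM50B was higher in shCon by log2 1.08 without and 0.60 with DHT, and KLC3, a kinesin light chain, lower (-0.84 and -1.07), though its Cy5 spot was saturated on 4 arrays and the size is uncertain. At least 2-fold differences numbered 2 higher and 8 lower without DHT, and 0 and 4 with DHT. S phase genes had medians of -0.10 and -0.26 (percentiles 0.05 and 0), although without DHT this was 0.53 with median centring; androgen-repressed genes lay at 0.12 and 0.15 (percentiles 98.47 and 99.96) and androgen-induced genes at 0.04 and -0.16, the former -0.03 with processed signals. Without DHT the comparison is the ratio of the dyes on 1 array, so dye effects enter it, and none of these values has a test.

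Apart from IFIT2, IFIT1 and OASL, genes picked for large changes of the Cy5 signal alone differed much less once the reference was taken into account. With DHT in shCon cells MGAT2 was at least 1.38-fold higher and SLC44A1 at least 1.18-fold lower, while LRP3, CDC123, HNRNPL and CERS2, with log2 ratios changed by -0.51, -0.02, -0.02 and 0.22, gave no bound. With DHT in shRNF6 over shCon cells NDUFB10 and APEX1 were dimmer too, but their direction is uncertain: the fitted shRNF6 change of NDUFB10 turned from -0.34 to 1.06 with processed signals, and that of APEX1 ranged from -0.55 to 1.00 over the alternatives. CLN3 is given no value, because its spot was saturated on 1 array and well above background on 2 of 5.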

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

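The tests in this part were all chosen after the results were seen. Their SEs are over genes, from 1 array per group, and hold no spread between arrays. The DHT response of ATP1B1 was -1.24 in shCon and near 0 in shRNF6 cells (0.06), a difference of 1.30 that was not tested. The median DHT response of interferon-stimulated genes also had opposite signs, -0.11 in shCon and 0.20 in shRNF6 cells, an untested difference of 0.31, while the median of the gene-by-gene differences was 0.09 (percentile 88.42, 10 members above 0 and 7 below); with processed signals the shRNF6 median was -0.20. The median of ribosomal protein genes did likewise, 0.02 in shCon and -0.05 in shRNF6 cells, an untested difference of -0.071, with a gene-by-gene median of -0.06. Negative-control spots, which the comparisons do not use, had right-side Cy5 medians of 240 on the shRNF6 array with DHT and 168.4 on that without, above the 118.7 of the next array.

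Interferon-stimulated genes were higher on both shRNF6 arrays. Uneven hybridisation is argued against by the 7 members whose probes lie on the evenly dim left side, with a median of 2.74 log2 in the smaller of the 2 comparisons (3.49 over 10 members on the right). Transduction as such is argued against by the 0.034 log2 of shCon over untransduced cells with DHT, against 2.83 for shRNF6 over shCon. A response to this hairpin or to this line cannot be told apart from loss of RNF6, because the labels give these cells 1 name, shRNF6, and do not say how many hairpins or lines it covers. Lower RNF6 therefore stays open as a hypothesis that these arrays did not test.

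Many genes were called between shRNF6 and shCon cells, 30.96% of those tested. On the left side 36.32% of 4537 genes were called, against 26.08% of 5011 on the right. This argues against calls that arose mainly at spots on the bright right side. Normalization was fitted over each whole array, so the left side is not free of the right side's brightness. Other effects of uneven hybridisation on the calls are therefore not excluded. Signals near background as the whole source are argued against by genes well above background in both channels on all arrays, of which 36.32% of 2803 were called. This share covers those genes alone and cannot show whether calls of dimmer genes come from background. How many of the calls are specific to RNF6 stays open, since the bright right side was on both shRNF6 arrays and neither shCon array.

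Genes lowered by DHT in untransduced cells were not lowered as a group in shRNF6 cells. Signals near background are argued against by the 45 of them measured on the 4 hairpin arrays, whose median difference was 0.46 (SE 0.05). Compressed ratios are argued against because raised genes kept 0.80 more of their shCon response than lowered genes did (SE 0.22). A lower starting level is argued against for the 29 genes that did not start lower in shRNF6 cells, whose median difference was 0.38 (SE 0.07), but it cannot be told apart for the 30 that did, whose starting median of -0.43 lay close to their shCon response of -0.48, nor was it excluded for the fixed androgen-repressed list, which started at -1.34. Loss of RNF6 may underlie the pattern as a hypothesis, and the effect was smaller with processed signals (0.27), a change whose cause was not tested.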

How the results depend on the processing

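Settings named as added were chosen after values had been seen. A slide block was not run, because each array had its own slide. No paired analysis was possible because no label pairs the samples. Leaving out an array was not run, since each group has 1 array and 3 arrays would leave 0 residual degrees of freedom. RNF6 and the interferon-stimulated genes have no value under the strictest filter, and genes lowered in untransduced cells none with median centring. The causes of the changes below were not tested, except that stricter filters leave fewer genes. Values as reported stand in brackets, counts are genes higher and lower, and fold counts use 2-fold. Of results that answer a comparison, 142 values stayed similar, 114 moved and 2 reversed. Of the named genes' values 389 stayed, 46 gained and 15 lost a call, 5 moved and 1 reversed. Aquantile scaling leaves log2 ratios unchanged, so its values could hardly move and add to the counts that stayed. The 1.5-fold threshold changes fold counts by construction. Dye effects of single genes enter every DHT fit that holds the untransduced array, so the counts of such fits may include them. These counts are therefore no measure of robustness.

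Agilent's processed signals gave, for the DHT fit, 0 higher (3), and for the shRNF6 fit 935 lower (1993). Fold counts were 97 and 23 for DHT in untransduced cells (13 and 7), 152 and 102 in shCon (8 and 5), 473 and 208 in shRNF6 (7 and 2); 1024 and 819 for shRNF6 over shCon without DHT (263 and 83), 1163 and 880 with DHT (276 and 54); and for shCon over untransduced 51 higher without DHT (2) and 72 and 71 with DHT (0 and 4). The difference of DHT responses was 0.0017 for raised genes, a reversal (-0.13), and 0.27 for lowered ones (0.41), and the correlation of responses 0.151 (0.242). RNF6 with DHT was -1.56 (-0.58). Fitted medians were 0.61 for androgen-induced genes with DHT (0.29), -0.34 for androgen-repressed ones (-0.16) and 4.61 for interferon-stimulated genes in shRNF6 (2.85). NDUFB10 in shRNF6 reversed to 1.06 (-0.34). Of its 2063 calls for shRNF6, 1237 were shared, 1195 in the same direction.

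Median centring gave 458 and 4192 for the shRNF6 fit (968 and 1993), and fold counts of 829 and 0 for DHT in untransduced cells, 18 higher in shCon, 950 lower for shRNF6 over shCon without DHT and 721 with DHT, and 956 and 1 for shCon over untransduced without DHT and 7 lower with DHT. The difference for raised genes reversed to 0.14, the correlation was 0.169, RNF6 without DHT -1.08 (-0.69), the medians 0.21, -0.23 and 3.15 in the order above, and p53 targets in shRNF6 reversed to -0.092 (0.36). Centring on the tested genes (added) gave 129 and 31 for the DHT fit, 1621 higher for shRNF6, 48 lower for shRNF6 over shCon without DHT, 1 higher for shCon over untransduced without DHT, and 2.94 for interferon-stimulated genes. With a spatial trend removed (added), the raised genes' difference was -0.036, the correlation 0.216 and the androgen-repressed median -0.10.

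Without background correction the DHT fit gave 24 and 8, fold counts were 4 and 0 for DHT in shRNF6, 52 and 28 lower for shRNF6 over shCon without and with DHT, and 0 higher for shCon over untransduced without DHT. Differences were -0.049 for raised and 0.53 for lowered genes, the correlation 0.201, RNF6 without DHT -0.52, and the androgen-induced and interferon medians 0.22 and 2.57. Without a filter the DHT fit gave 92 and 12 and the shRNF6 fit 2133 higher, with fold counts of 29 higher for DHT in shCon, 4 lower in shRNF6, and 27 lower and 1 higher for shCon over untransduced without and with DHT; the correlation was 0.174 and the 3 medians 0.20, -0.094 and 2.57. With signals well above background in both channels on all arrays, the DHT fit gave 0 higher and the shRNF6 fit 389 and 465, with fold counts of 6 higher for DHT in untransduced cells, 2 and 2 in shCon, 4 and 0 in shRNF6, 99 and 28 for shRNF6 over shCon without DHT, 105 and 16 with DHT, and 0 and 3 for shCon over untransduced without DHT. The raised genes' difference was -0.060, the correlation 0.301, and the androgen medians 0.18 and -0.25.

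With the mean of a gene's probes the DHT fit gave 8 and 1, fold counts were 4 lower for DHT in untransduced and 2 in shCon cells, and the androgen-induced and interferon medians 0.37 and 2.61. The DHT fit gave 17 higher with an intensity trend, 280 and 36 with all 5 arrays, 650 and 377 with untransduced and shCon arrays, and 313 and 50 with untransduced and shRNF6 arrays. At 1.5-fold, counts were 99 and 59 for DHT in untransduced cells, 63 and 23 in shCon, 87 and 20 in shRNF6, 514 and 620 for shRNF6 over shCon without DHT, 597 and 544 with DHT, and 7 and 17 then 9 and 19 for shCon over untransduced without and with DHT. The RNF6 fit ranged from -1.15 to -0.49 over the alternatives, with adjusted p from 7.03e-05 to 0.0215.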

Other observations

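Gene lists in this part were chosen after the values were seen, and their counts come from the same shRNF6 fit over all genes. Genes of antigen presentation were higher in shRNF6 than in shCon cells: 14 of 15 measured members rose, with medians of 1.78 without and 1.75 with DHT (percentile 100 in both). Besides B2M (log2 2.74) these were HLA-C (2.41) and HLA-B (2.14), class I heavy chains, and TAP1 (2.16), a peptide transporter, while NLRC5, a regulator of class I genes, lay at 0.05 and did not pass. The HLA genes are similar in sequence, so which of them changed is uncertain. Of 20 listed NF-kB targets 8 were measured and 7 rose, with medians of 1.43 and 1.73. BIRC3, NFKBIE and SOD2, and PSMB8 in the antigen presentation list, passed the brightness filter through the shRNF6 arrays alone. RELB, above background in Cy5 on 3 arrays, would not have passed it without the shRNF6 arrays. The shares that rose are therefore partly set by that filter. BIRC3, an inhibitor of apoptosis, was at least 6.01-fold higher without and at least 2.35-fold with DHT, with Cy3 well above background on 0 arrays. The inhibitor NFKBIA rose by log2 2.27, and BCL3 4.11-fold without and at least 4.22-fold with DHT. TRAF1 lay at 0.08 and did not pass.

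Of 21 listed immediate early genes 10 were measured. Of these 7 rose and 1 fell in shRNF6 cells, with a fitted median of 0.95. KLF4, ID1 and DUSP1 would not have passed the brightness filter without the shRNF6 arrays. The share that rose is therefore partly set by that filter. KLF4 was at least 5.07-fold higher without and at least 7.59-fold with DHT, ID1 3.81-fold and at least 6.18-fold and JUNB 4.23-fold and at least 3.95-fold. Cy3 was well above background on 0 arrays for KLF4 and ID1, so the sizes of their changes are uncertain. MYC was at least 2.4-fold and at least 2.99-fold lower. None of the 3 measured leukocyte markers passed (median 0.03). Over all spots the log ratios of the shRNF6 arrays correlated at 0.84 with each other. Those of the other 3 arrays correlated at 0.44 to 0.61, and across these sets at 0.05 to 0.18. Only 13.39% and 13% of probes were well above background in Cy5 on the shRNF6 arrays without and with DHT. These arrays also shared a bright right side, so shared background may enter the 0.84.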
